A study of Mus musculus with 18 samples.

How the data were processed

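Gene expression was measured by RNA sequencing in 18 mouse libraries of B progenitors from 4 sources. Libraries were made from total RNA with an Ion Total RNA-Seq kit after removal of ribosomal RNA, per the labels' protocols. The authors deposited 1 table with the read count of each of 12477 genes in each library, in the column layout of featureCounts, with gene positions. The submitters' processing notes name STAR 2.4.2a, featureCounts of Subread 1.5.0, edgeR and genome build mm10, without giving their settings. The counts are whole numbers and were not normalized, per the file headers and the values. Every gene in the table has over 1 CPM in at least 4 libraries, so genes with lower counts were left out before deposition. The authors also deposited log2 fold changes and p-values with false discovery rates for the 6 pairs of sources. These were used only to check the counts and the direction of each contrast. A repeat of their fit without a term for library series gave a Pearson r of 1 across genes for the log2 fold changes of bone marrow against ES-derived cells. Across genes, 19 symbols had been turned into dates and 1 symbol occurred more than once. No immunoglobulin heavy chain V gene is listed, so the planned share of V gene families could not be computed.

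Totals ran from 9574825 to 15713695 counts per library. Counts were scaled with TMM factors (range 0.903 to 1.10) and tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F-tests with Benjamini-Hochberg adjustment, two-sided, and a gene was called at an adjusted p under 0.05. The filter on low counts removed no gene. The model had a mean for each source and a term for library series, since the codes in the titles put 12 libraries in a first series and 6 in a second. Fetal liver is only in the first series and bone marrow only in the second. ES library 5 and yolk sac library 5 link them. The term called 1 gene (Myh6), with 342 genes at an unadjusted p under 0.05. The change of the ES to yolk sac difference between series was called for 0 genes by edgeR, with 527 at an unadjusted p under 0.05. Levels are CPM on the TMM-scaled library totals, given as mean ± SD. Log2 fold changes of single genes carry their standard error (SE).

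Before the data were examined, the design, the alternatives, 25 gene lists and a rule for the genes to be named were fixed. The rule took, in each of 4 comparisons, up to 10 genes with the largest change in each direction among called genes with a mean of at least 5 CPM on the higher side and no overlap between the libraries of both sides, without clone names, small RNAs and receptor segments. It added up to 4 called genes of each list with the largest change, Cd19 and Ptprc in every comparison, and Lin28b, Hmga2, Igf2bp3, Arid3a, Dntt, Bhlhe41, H2-Aa and Cd74 in the comparison with bone marrow. Hmga2 is not in the table. Other genes that the text names were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and lists with under 3 measured members were not tested. Each call was repeated with an estimated correlation and with the rotation test fry. Some lists share genes, so their tests are not independent. The homing and adhesion list shares Ccr7, Cxcr5, Sell and S1pr1 with the mature B-2 list. The imprinted list shares genes with the fetal program list, H19 and Igf2 among them. The share of counts from genes of other cell types was compared by exact permutation tests, two-sided. This was done for lists with a mean share over 0.1 percent of counts in any source.

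A fold against a source with no counts was set against a floor of 3 counts over the source. With 1 to 3 counts, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only. Scripts were tested on simulated counts, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of these, 48 and 94 were recovered for prenatal sources against bone marrow, 72 and 99 for ES-derived against yolk sac cells, 72 and 94 for ES-derived against fetal liver cells, and 71 and 100 for yolk sac against fetal liver cells. The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, no series term, contrasts within a series, the compared sources alone, fewer features, replicate letters as a block, and each library left out. Leaving out both ES library b and yolk sac library b, and leaving out genes that track stroma, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.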

Results

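B progenitors of 4 sources were sequenced in 18 mouse libraries. There were 5 libraries of cells made from the embryonic stem (ES) cell line D3, 5 from yolk sac of embryonic day 10, 4 from fetal liver and 4 from adult bone marrow. Tissue donors were C57BL/6 mice. By their labels, all cells grew on OP9, a stromal line that supports B cell development, with IL-7 and Flt3 ligand. ES-derived cells had been sorted as Flk1+ mesoderm, or in library b as VE-cadherin+ endothelium, and spent 13 to 16 days on OP9. Yolk sac cells spent 10 days and fetal liver cells 6 days, and the time of bone marrow cells is not given. The submitters describe the first 3 sources, called prenatal here, as biased to B-1 cells and bone marrow as biased to B-2 cells. The subtype label of the bone marrow libraries reads B-1, against their titles.

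Cd19, which marks the B lineage and the sorting gate, stood at 801 ± 55.5 CPM in ES-derived (SD, n = 5), 956 ± 314 in yolk sac (n = 5), 1273 ± 53.8 in fetal liver (n = 4) and 826 ± 37.2 CPM in bone marrow cells (n = 4). The first principal component held 53% of the variance and set bone marrow apart, and the second held 19.4% and set ES-derived cells apart from the others. Yolk sac library b lay between the other yolk sac libraries and bone marrow. Some libraries of a source were close to each other. The counts of ES c and ES d differed by 3.22 times sampling noise, those of fetal liver a and c by 3.38 and those of yolk sac a and 5 by 4.14, against medians of 10.7, 9.39 and 16.9 over all pairs of each source. No label says which libraries come from separate animals or cultures, so the p-values measure the spread between libraries.

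**Figure D1:**
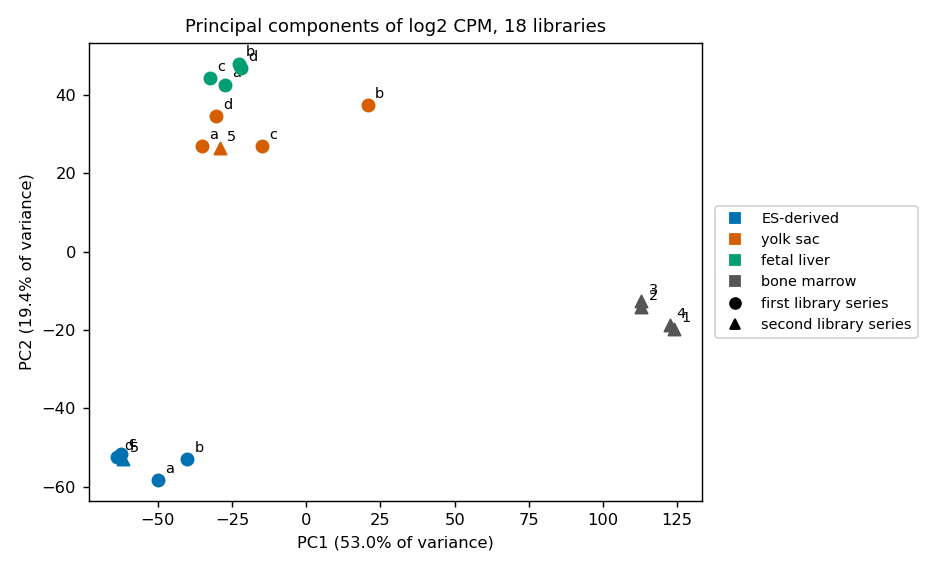
Principal components of log2 CPM, with 1 point per library, colour for the source and shape for the library series. Bone marrow lies apart on the first component (53% of the variance), ES-derived cells lie apart on the second (19.4%), and the second-series ES-derived and yolk sac libraries (5) lie with their sources.

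The first question was how the prenatal, B-1 biased progenitors differed from B-2 biased bone marrow progenitors. Lin28b, an RNA-binding protein that blocks let-7 maturation (chromosome 10, 45376619 to 45470201, mm10), stood at 110 ± 23.3 CPM in ES-derived (SD, n = 5), 35.6 ± 4.14 in yolk sac (n = 5) and 29.7 ± 2.25 in fetal liver cells (n = 4). The 4 bone marrow libraries held 3 Lin28b counts together, a ratio of 904 (95% counting interval 309 to 4384). Leaving out 1 library gave ratios from 636 (without bone marrow 3) to 2160 (without bone marrow 1). Dntt, the terminal transferase that adds nucleotides at V(D)J joins (chromosome 19, 41029275 to 41059525), showed the opposite, with 247 ± 136 CPM in bone marrow and 0.859 ± 0.440, 2.26 ± 2.57 and 1.33 ± 0.167 CPM in ES-derived, yolk sac and fetal liver cells. H2-Aa, a chain of MHC class II, stood at 162 ± 9.29 CPM in bone marrow and at 1.20 ± 1.39, 9.62 ± 5.87 and 1.30 ± 0.332 CPM in the same order. For each of these genes, every prenatal library lay on one side of every bone marrow library. In edgeR's quasi-likelihood test, with the mean of the 3 prenatal sources set against bone marrow, 6877 genes had an adjusted p under 0.05, of which 3662 were higher and 3215 lower in the prenatal sources. The groups did not overlap for 34.3% of genes, where chance gives 0.0654% if libraries are independent. No label states that, and the levels compared here were not adjusted for library series.

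Of 10 measured genes of the fetal program list, 7 were higher in the prenatal sources, 0 were lower and 3 were not called (camera, adjusted p = 3.4e-07), with the same counts adjusted over the list alone. The call held with an estimated correlation (adjusted p = 0.00678 with an estimated correlation). Igf2bp3, an mRNA-binding protein of fetal tissues (chromosome 6, 49085218 to 49214954), stood at 107 ± 11.2, 116 ± 29.4 and 115 ± 6.72 CPM in the prenatal sources and at 6.98 ± 0.789 CPM in bone marrow (log2 fold change 3.87, SE 0.19). Igf2bp1 rose with a log2 fold change of 5.96 (SE 0.95). The imprinted genes H19 and Igf2, a non-coding RNA and a growth factor, were higher by 7.60 (SE 0.92) and 3.93 (SE 0.71) on the log2 scale. H19 ranged from 42.0 ± 23.5 CPM in ES-derived cells to 1996 ± 1202 in yolk sac and 1067 ± 393 in fetal liver cells, against 3.07 ± 2.25 CPM in bone marrow. Arid3a, a transcription factor tied to fetal B cells, had a log2 fold change of 0.06 (SE 0.18, adjusted p = 0.783). Of 18 imprinted genes, 9 were higher and 1 was lower (adjusted p = 0.0093; adjusted p = 0.25 with an estimated correlation), among them Grb10 (log2 fold change 4.53, SE 0.26) and Ndn (5.85, SE 0.77). Genes of OP9-like stroma moved with this group: they took 0.142 ± 0.0630% of counts in ES-derived, 0.109 ± 0.0501% in yolk sac and 0.159 ± 0.0299% in fetal liver libraries, and 0.00368 ± 0.00101% in bone marrow libraries.

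MHC class II genes were lower in the prenatal sources in 10 of 11 cases, with the same count adjusted over the list alone (camera, adjusted p = 1.18e-09; adjusted p = 0.0133 with an estimated correlation). The largest changes were in H2-Aa (log2 fold change -7.23, SE 0.78), H2-Eb1 (-6.88, SE 0.81) and Ciita, the transactivator of the class (-6.40, SE 0.39), and the invariant chain Cd74 followed (-4.53, SE 0.54). The list of mature B-2 cells held 11 lower and 1 higher of 13 genes (adjusted p = 5.64e-05; adjusted p = 0.00678 with an estimated correlation), such as the costimulatory receptor Cd40 (-5.05, SE 0.64). The list of mature B-1 cells split, with 4 higher and 6 lower of 16 (adjusted p = 0.89). S100a6 was higher (4.49, SE 0.50) and Bhlhe41, a transcription factor of mature B-1 cells, was lower (-3.57, SE 0.47). Among 22 B lineage transcription factors, 15 were lower and 2 higher, or 16 and 2 adjusted over the list alone (adjusted p = 7.56e-05; adjusted p = 0.382 with an estimated correlation). Bach2, a repressor of plasma cell fate, stood at 1327 ± 227 CPM in bone marrow and at 31.1 ± 4.28, 104 ± 77.7 and 137 ± 58.0 CPM in the prenatal sources, and Ikzf3, Foxo1 and Spi1 fell by 2.26 (SE 0.29), 2.21 (SE 0.33) and 2.26 (SE 0.28) on the log2 scale. Among 24 B progenitor surface and pre-BCR genes, 13 were lower and 4 higher (adjusted p = 0.0739). Il2ra (-5.44, SE 0.48), Cd72 (-4.80, SE 0.70) and Cd2 (-3.71, SE 0.26) were lower and the surrogate light chain gene Vpreb2 was higher (4.12, SE 0.37). Ptprc, which encodes the pan-leukocyte CD45, was lower (-1.33, SE 0.14) and Cd19 was not called (0.13, SE 0.21, adjusted p = 0.616).

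V(D)J recombination and end joining genes went both ways, with 4 higher and 6 lower of 14 (adjusted p = 0.485). Polm, a polymerase that acts at coding joins, was lower (-5.52, SE 0.57) and Poll was higher (1.65, SE 0.22). Homing and adhesion genes were lower in 12 of 16 cases and higher in 3 (adjusted p = 0.00589; adjusted p = 0.0301 with an estimated correlation), with the chemokine receptor Cxcr4 at -3.03 (SE 0.25). The interferon response list was lower in 15 of 29 cases and higher in 0 (adjusted p = 0.00851; adjusted p = 0.52 with an estimated correlation; 0.106 without yolk sac library 5). MHC class I and presentation genes were lower in 7 of 13 cases and higher in 1 (adjusted p = 0.0444; adjusted p = 0.503 with an estimated correlation). The interferon response example Oas3 fell by 6.30 (SE 1.29) on the log2 scale and the class I gene H2-K1 by 1.74 (SE 0.31). The MHC class I and presentation call passed 0.05 by little: its adjusted p was 0.0533 without yolk sac c, 0.0531 without yolk sac d, 0.167 without yolk sac 5, 0.0541 without fetal liver d, and 0.0562 and 0.0607 without bone marrow 2 and 3. The IL-7 and STAT5 response list held 4 higher and 7 lower of 15 genes, or 5 and 7 adjusted over the list alone (adjusted p = 0.363), with Socs2 higher (3.18, SE 0.32) and Socs1 lower (-2.57, SE 0.34). Its median turned from -0.09 to 0.06 with upper quartile scaling.

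Glycolysis and hypoxia genes were higher in the prenatal sources in 20 of 23 cases and lower in 0, with the same counts adjusted over the list alone (camera, adjusted p = 2.6e-13; adjusted p = 0.177 with an estimated correlation). Aldoa, an aldolase of glycolysis, stood at 1283 ± 261, 2626 ± 735 and 1944 ± 132 CPM in the prenatal sources and at 122 ± 3.34 CPM in bone marrow (log2 fold change 4.22, SE 0.24). The lactate transporter Slc16a3 (7.69, SE 0.65) and the glycolytic kinase Pgk1 (3.80, SE 0.29) were higher as well. Cell cycle genes were higher in 8 and lower in 4 of 30 cases (adjusted p = 0.254), with the thymidylate synthase Tyms at 1.20 (SE 0.13). The p53 response list split into 7 higher and 5 lower of 14 (adjusted p = 0.485), with Phlda3 higher (2.85, SE 0.36) and Bbc3 lower (-1.74, SE 0.28). Hox and Meis genes were lower in 3 of 5 cases (adjusted p = 0.0632), with Pbx1 at -2.67 (SE 0.30). The stroma share given above was higher in the same prenatal libraries.

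Genes of OP9-like stroma were higher in the prenatal sources in 23 of 23 cases (camera, adjusted p = 2.56e-15; adjusted p = 0.177 with an estimated correlation). Col6a1 rose by 9.09 (SE 0.77) and the stromal chemokine Cxcl12 by 8.70 (SE 0.70) on the log2 scale. Cyp1b1, which is not on this list and had 0 counts in bone marrow, was at least 463-fold higher (at least 325-fold without bone marrow 3). The mean share of stromal counts was higher by 0.131 percentage points, and 1 of 3060 splits gave as much (exact permutation p = 0.000327, the smallest possible; 0.00458 adjusted over 14 tests). Myeloid genes were lower in 11 and higher in 0 of 22 cases (adjusted p = 0.0093; adjusted p = 0.405 with an estimated correlation). The granule gene Mpo stood at 54.5 ± 13.9 CPM in bone marrow and under 1 CPM on average in each prenatal source. Yolk sac went the other way in part: the myeloid share was 0.0319 ± 0.0228% there and 0.0160 ± 0.00479% in bone marrow, and C1qb stood at 40.3 ± 34.0 against 0.490 ± 0.252 CPM. T, NK and innate lymphoid genes were lower in 3 of 8 cases (adjusted p = 0.136), with Id2 at -4.44 (SE 0.50). Megakaryocyte genes were lower in 2 of 3 (adjusted p = 0.254), endothelial genes higher in 1 and lower in 1 of 6, or 0 and 1 adjusted over the list alone (adjusted p = 0.89), and plasma cell genes higher in 1 and lower in 3 of 6 (adjusted p = 0.324). Only Car2 and Tfrc of the erythroid list were measured and 0 genes of the pluripotent list, so neither was tested as a list with camera. Car2, a carbonic anhydrase, was higher (2.48, SE 0.21). The share of counts from Car2 and Tfrc was higher in the prenatal sources by 0.0528 percentage points (exact permutation p = 0.00882; adjusted p = 0.0247). The sex-linked list held 4 higher and 1 lower of 5 (adjusted p = 0.0854): Xist stood at 1295 ± 254 CPM in bone marrow, where the Y-linked Eif2s3y had 2 counts. The list test is directional and pools Xist with Y-linked genes. These values point to female bone marrow cells. With Y-linked genes higher in the prenatal sources, sex is confounded with source in this comparison, and its effect was not tested.

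**Figure D2:**
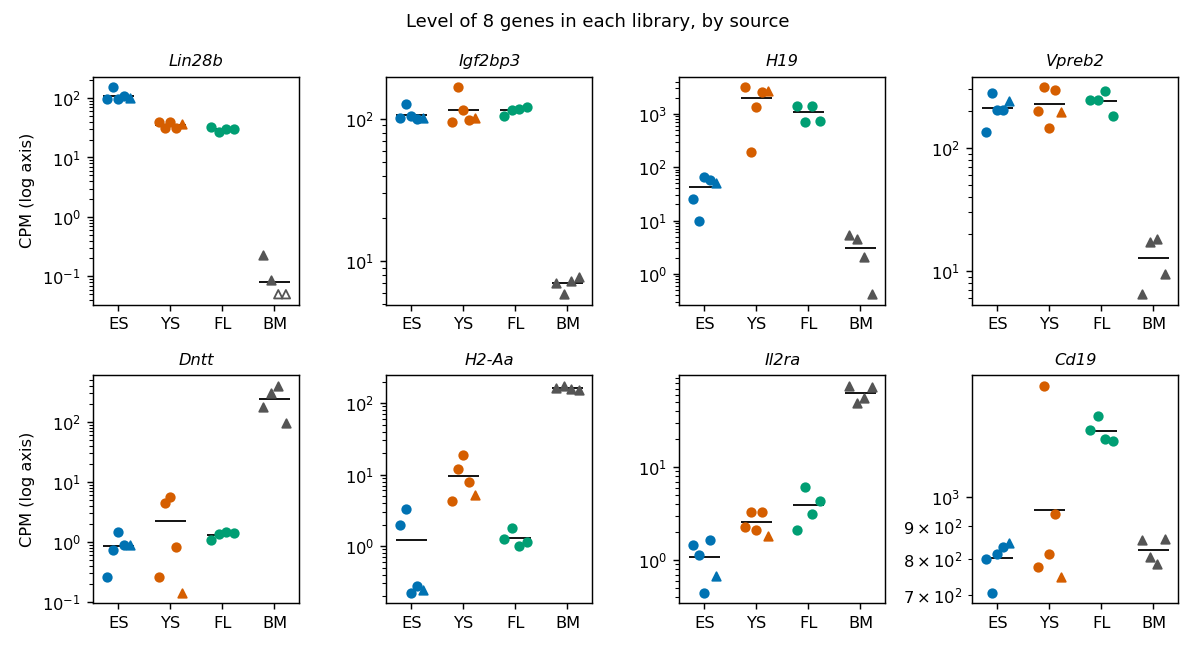
TMM-scaled CPM of selected genes in each library (log axis), by source, with a line at the mean of each source. Lin28b and Igf2bp3 lie higher and Dntt and H2-Aa lower in all 14 prenatal libraries than in the 4 bone marrow libraries.

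Fetal liver and bone marrow share no library series, so this comparison rests on ES library 5 and yolk sac library 5. Within the second series, those 2 libraries set against bone marrow gave 7277 genes, 3801 higher and 3476 lower. By pair of sources, 7502 genes differed between ES-derived and bone marrow cells (3980 higher, 3522 lower), 6541 between yolk sac and bone marrow cells (3539 and 3002) and 5606 between fetal liver and bone marrow cells (2956 and 2650). The count for yolk sac against bone marrow was 4040 without yolk sac library 5. Upper quartile scaling shifted the median log2 fold change of all genes by 0.14 for the prenatal sources against bone marrow and by 0.17 for fetal liver against bone marrow. With it, 4328 genes were higher and 2737 lower in the first, and 3634 higher and 2095 lower in the other. ES-derived against bone marrow cells then gave 4589 higher and 3064 lower, and yolk sac against bone marrow cells 4073 and 2580.

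The second question was how close cells made from ES cells come to yolk sac progenitors. Lin28b was higher in ES-derived cells by 1.63 (SE 0.16) and Igf2bp1 by 3.38 (SE 0.53) on the log2 scale, with Igf2bp1 at 76.8 ± 41.5 against 7.60 ± 5.88 CPM (n = 5 and 5). The B cell surface gene Cd2 (chromosome 3, 101275908 to 101287939) stood at 4.23 ± 0.683 in ES-derived and 51.5 ± 12.3 CPM in yolk sac cells, and Ms4a1, which encodes CD20, fell by 3.73 (SE 0.33). Eda2r, a receptor induced by p53, rose by 4.46 (SE 0.40). In edgeR's quasi-likelihood test 3660 genes had an adjusted p under 0.05, of which 1652 were higher and 2008 lower in ES-derived cells. Of all genes 18.5% separated the libraries without overlap, where chance gives 0.794% if libraries are independent.

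All 11 MHC class II genes were lower in ES-derived cells (camera, adjusted p = 7.16e-12; adjusted p = 0.00346 with an estimated correlation), with Cd74 at 7.72 ± 4.47 against 81.0 ± 47.6 CPM. MHC class I and presentation genes were lower in 12 of 13 cases (adjusted p = 2.54e-08; adjusted p = 0.0653 with an estimated correlation), such as H2-T23 (-1.74, SE 0.22) and the peptide transporter Tap1 (-1.29, SE 0.17). Interferon response genes were lower in 24 of 29 cases and higher in 1 (adjusted p = 1.46e-07; adjusted p = 0.282 with an estimated correlation), with Oasl1 at -4.13 (SE 0.61). Homing and adhesion genes were lower in 11 of 16 cases, or 12 adjusted over the list alone (adjusted p = 2.59e-08; adjusted p = 0.000589 with an estimated correlation), such as the integrin Itgal (-3.39, SE 0.31) and Ccr7 (-2.44, SE 0.13), a receptor for lymph node entry. Mature B-2 genes were lower in 8 of 13 cases, or 12 adjusted over the list alone (adjusted p = 3.41e-06; adjusted p = 0.00259 with an estimated correlation), with the follicle receptor Cxcr5 at -2.28 (SE 0.30). B progenitor surface and pre-BCR genes were lower in 9 and higher in 2 of 24 cases, or 11 and 2 adjusted over the list alone (adjusted p = 5.18e-05; adjusted p = 0.154 with an estimated correlation), with the kinase Blk at -2.13 (SE 0.34). Ptprc was lower (-0.74, SE 0.09) and Cd19 was not called (-0.25, SE 0.15, adjusted p = 0.241).

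The p53 response list was higher in ES-derived cells in 10 of 14 cases, or 11 adjusted over the list alone, and lower in 1 (camera, adjusted p = 2.89e-06; adjusted p = 0.00247 with an estimated correlation). Zmat3 (2.88, SE 0.23) and Phlda3 (2.77, SE 0.26) rose and Pmaip1, which promotes apoptosis, fell by 1.56 (SE 0.21). Hox and Meis genes were higher in 3 and lower in 1 of 5 (adjusted p = 0.000403; adjusted p = 0.023 with an estimated correlation), with Pbx3 at 2.75 (SE 0.26) and Meis1 at 1.57 (SE 0.24). Imprinted genes were higher in 9 and lower in 2 of 18 (adjusted p = 0.00108; adjusted p = 0.128 with an estimated correlation), where Peg10 rose by 3.14 (SE 0.35) and H19 fell by 5.56 (SE 0.69). Glycolysis and hypoxia genes were lower in 15 of 23 cases, or 18 adjusted over the list alone (adjusted p = 2.89e-06; adjusted p = 0.33 with an estimated correlation), with Aldoc at -2.32 (SE 0.24) and Pfkp at -1.44 (SE 0.26). The fetal program list split into 4 higher and 3 lower of 10 (adjusted p = 0.34). Of the cell cycle list, 1 gene was higher and 2 were lower of 30 (adjusted p = 0.936), with a median of 0.00 that turned to -0.01 with RLE scaling.

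Myeloid genes were lower in ES-derived cells in 14 of 22 cases, or 15 adjusted over the list alone (camera, adjusted p = 9.37e-08; adjusted p = 0.0653 with an estimated correlation). The macrophage genes C1qb and Csf1r stood at 40.3 ± 34.0 and 38.4 ± 31.3 CPM in yolk sac and at 0.511 ± 0.592 and 0.783 ± 0.767 CPM in ES-derived libraries. The myeloid share of counts was 0.0319 ± 0.0228% in yolk sac and 0.00287 ± 0.00161% in ES-derived libraries, a difference in the direction of the MHC and interferon lists. The share of counts from Car2 and Tfrc was higher in ES-derived cells by 0.0700 percentage points (exact permutation p = 0.00794; adjusted p = 0.0247). T, NK and innate lymphoid genes were lower in 4 of 8 (adjusted p = 0.0122; adjusted p = 0.128 with an estimated correlation), with the kinase Lck at -1.67 (SE 0.21). The sex-linked list was lower in 4 of 5 (adjusted p = 0.0449; adjusted p = 0.282 with an estimated correlation). Its adjusted p was 0.0678 without ES a, 0.0604 without ES b, 0.0712 without ES 5, 0.0791, 0.084 and 0.071 without yolk sac a, c and 5, and 0.0504 without fetal liver b. The largest single changes included Trim12a, with 0 counts in ES-derived cells and at least 657-fold lower (at least 512-fold without ES 5). Fzd6, a Wnt receptor, had a ratio of 1449 (95% counting interval 495 to 7028) in favour of yolk sac. Leaving out 1 library gave Fzd6 ratios from 1030 (without yolk sac b) to 3478 (without ES b). Rprl3 (8.49, SE 0.35), St6galnac2 (7.85, SE 0.48) and the guanylate-binding protein gene Gbp2b (6.01, SE 0.45) were higher in ES-derived cells. The ES line and the mice differ in strain by their labels, and a fit to the ES-derived and yolk sac libraries alone called 2390 genes.

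**Figure D3:**
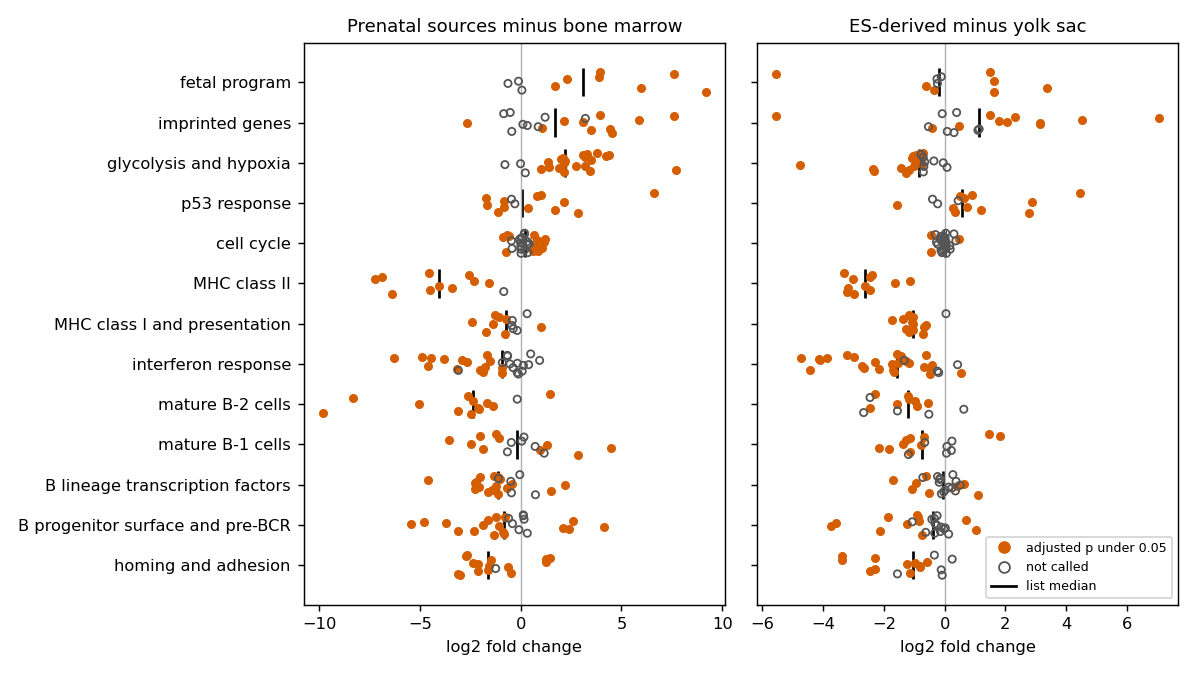
Log2 fold change of each measured member of 13 gene lists, for the prenatal sources minus bone marrow and for ES-derived minus yolk sac cells. Filled points passed an adjusted p under 0.05 and bars mark list medians; MHC class II members lie below 0 in both comparisons, with 10 of 11 called in the first and 11 of 11 in the second.

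Against fetal liver progenitors, which were taken from the embryo as CD19+ cells, ES-derived cells differed at 4854 genes, 2449 higher and 2405 lower (edgeR's quasi-likelihood test, adjusted p under 0.05). With upper quartile scaling 2299 were higher and 2494 lower, so the larger side turned. Days on OP9 also differ between ES-derived and fetal liver cells, and their effect was not tested. Of all genes 41.2% separated the libraries, where chance gives 1.59% if libraries are independent. Lin28b was higher in ES-derived cells by 1.90 (SE 0.17) and Igf2bp1 by 3.92 (SE 0.59) on the log2 scale. Ms4a1 stood at 4.86 ± 3.57 CPM in ES-derived (n = 5) and 138 ± 24.3 CPM in fetal liver cells (n = 4), and Cd2 fell by 3.84 (SE 0.18). The replication helicase gene Mcm5 was higher in ES-derived cells, at 931 ± 96.2 against 489 ± 41.7 CPM (log2 fold change 0.93, SE 0.16). The mast cell protease gene Tpsb2 had 0 counts in fetal liver, and mast cell genes were not tested as a list. Tpsb2 stood at 163 and 57.2 CPM in ES a and b and at 6.79, 6.52 and 6.68 CPM in ES c, d and 5.

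Mature B-2 genes were lower in ES-derived cells in 8 of 13 cases, or 9 adjusted over the list alone (camera, adjusted p = 1.71e-08; adjusted p = 0.000559 with an estimated correlation), with Bank1, a B cell scaffold protein, at -2.11 (SE 0.14). Homing and adhesion genes were lower in 9 and higher in 1 of 16, or 10 and 1 adjusted over the list alone (adjusted p = 3.82e-07; adjusted p = 0.000576 with an estimated correlation), with Ccr7 at -2.86 (SE 0.14) and Itgal at -3.38 (SE 0.32). MHC class II genes were lower in 9 of 11 (adjusted p = 1.1e-05; adjusted p = 0.0312 with an estimated correlation). B progenitor surface and pre-BCR genes were lower in 12 and higher in 1 of 24 (adjusted p = 6.41e-05; adjusted p = 0.203 with an estimated correlation). The p53 response list was higher in 9 and lower in 2 of 14 (adjusted p = 0.00043; adjusted p = 0.00869 with an estimated correlation), with Zmat3 at 2.27 (SE 0.24). Cell cycle genes were higher in 15 and lower in 0 of 30, or 15 and 1 adjusted over the list alone (adjusted p = 0.00188; adjusted p = 0.686 with an estimated correlation), with Mcm3 at 0.79 (SE 0.13) and Mcm7 at 0.75 (SE 0.12). Interferon response genes were lower in 9 and higher in 1 of 29 (adjusted p = 0.00403; adjusted p = 0.701 with an estimated correlation), such as the RNA sensor Ddx58 (-1.58, SE 0.19). Hox and Meis genes were higher in 3 of 5 (adjusted p = 0.00736; adjusted p = 0.084 with an estimated correlation), with Pbx3 at 2.59 (SE 0.28). The sex-linked list was lower in 4 of 5 (adjusted p = 0.0133; adjusted p = 0.25 with an estimated correlation), with Kdm5d at -4.59 (SE 0.82). The stroma share of counts differed by -0.0163 percentage points between ES-derived and fetal liver libraries (exact permutation p = 0.698 over 126 splits; adjusted p = 0.698). The share of Car2 and Tfrc was higher by 0.0518 percentage points (exact permutation p = 0.00794; adjusted p = 0.0247). Ptprc (-0.73, SE 0.10) and Cd19 (-0.64, SE 0.17) were lower in ES-derived cells. Csf2rb, a cytokine receptor chain on the myeloid list, was lower (-4.05, SE 0.42), while the myeloid list was not called (adjusted p = 0.781).

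The last comparison set yolk sac against fetal liver progenitors. These sources also differ in embryonic day and in days on OP9, which cannot be told apart from tissue here. H2-K1, a classical MHC class I gene (chromosome 17, 33996012 to 34000333), stood at 937 ± 222 CPM in yolk sac (SD, n = 5) and 196 ± 21.9 CPM in fetal liver cells (n = 4). MHC class I and presentation genes were higher in yolk sac cells in 9 of 13 cases and lower in 0 (camera, adjusted p = 1.06e-16; adjusted p = 0.0602 with an estimated correlation), and H2-Q4 and H2-D1 rose by 2.12 (SE 0.25) and 1.90 (SE 0.20). Glycolysis and hypoxia genes were higher in 15 and lower in 1 of 23, or 17 and 1 adjusted over the list alone (adjusted p = 7.01e-10; adjusted p = 0.386 with an estimated correlation), with the oxygen sensor Egln3 at 2.56 (SE 0.35) and hexokinase Hk2 at 1.97 (SE 0.39). Cell cycle genes were higher in 13 and lower in 0 of 30, or 15 and 0 adjusted over the list alone (adjusted p = 3e-07; adjusted p = 0.461 with an estimated correlation), with Mcm7 at 0.74 (SE 0.12) and Pcna at 0.69 (SE 0.14). Mature B-2 genes were lower in 5 of 13, or 7 with 1 higher adjusted over the list alone (adjusted p = 0.00559; adjusted p = 0.0602 with an estimated correlation), with Bank1 at -0.92 (SE 0.14). Lin28b (0.27, SE 0.17, adjusted p = 0.288) and Igf2bp3 (0.04, SE 0.14, adjusted p = 0.888) were not called, nor were Cd19 (-0.39, SE 0.16, adjusted p = 0.117) and Ptprc (0.01, SE 0.10, adjusted p = 0.947).

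Myeloid genes were higher in yolk sac cells in 12 of 22 cases and lower in 0 (camera, adjusted p = 2.7e-09; adjusted p = 0.117 with an estimated correlation). The macrophage genes C1qb (8.42, SE 0.80), Adgre1 (7.36, SE 0.86) and Csf1r (7.10, SE 0.72) were among them. C1qb stood at 58.3, 86.7 and 41.1 CPM in yolk sac b, c and d and at 10.7 and 4.76 CPM in a and 5, while H2-K1 stood at 1333 CPM in b and at 818 to 854 CPM in the others. T, NK and innate lymphoid genes were higher in 2 of 8, or 4 adjusted over the list alone (adjusted p = 0.00288; adjusted p = 0.137 with an estimated correlation), with Id2 at 2.61 (SE 0.36). Genes of the interferon response were higher in 7 and lower in 1 of 29, or 8 and 1 adjusted over the list alone (adjusted p = 0.0153; adjusted p = 0.809 with an estimated correlation). MHC class II genes were higher in 4 and lower in 1 of 11, or 5 and 1 adjusted over the list alone (adjusted p = 0.0488; adjusted p = 0.461 with an estimated correlation). Each of these calls was lost without yolk sac library b, with an adjusted p of 0.383 for interferon response and 0.509 for MHC class II, and without yolk sac library c, at 0.286 and 0.0901. The MHC class II call was also lost without ES a, fetal liver b or d, or any bone marrow library (camera, adjusted p from 0.0558 to 0.0679). Without both ES b and yolk sac b, 2 of the 8 list calls of this comparison were lost, MHC class II among them (camera, adjusted p = 0.368). Without the series term the adjusted p was 0.0609 for interferon response and 0.191 for MHC class II, and fry gave 0.322 for interferon response. H2-Aa was higher in yolk sac cells by 3.08 (SE 0.53) and Trpc4, a calcium channel gene, was lower (-2.71, SE 0.36). In all, 1993 genes had an adjusted p under 0.05 in edgeR's quasi-likelihood test, 1123 higher and 870 lower in yolk sac cells. With upper quartile scaling 923 were higher and 1070 lower, so the larger side turned. Of all genes 14.3% separated the libraries, where chance gives 1.59% if libraries are independent. The count depended on single libraries: 3712 genes were called without yolk sac b, 1197 without fetal liver b and 989 without fetal liver d, 4081 without both ES b and yolk sac b, and 665 in a fit to yolk sac and fetal liver libraries alone.

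**Figure D4:**
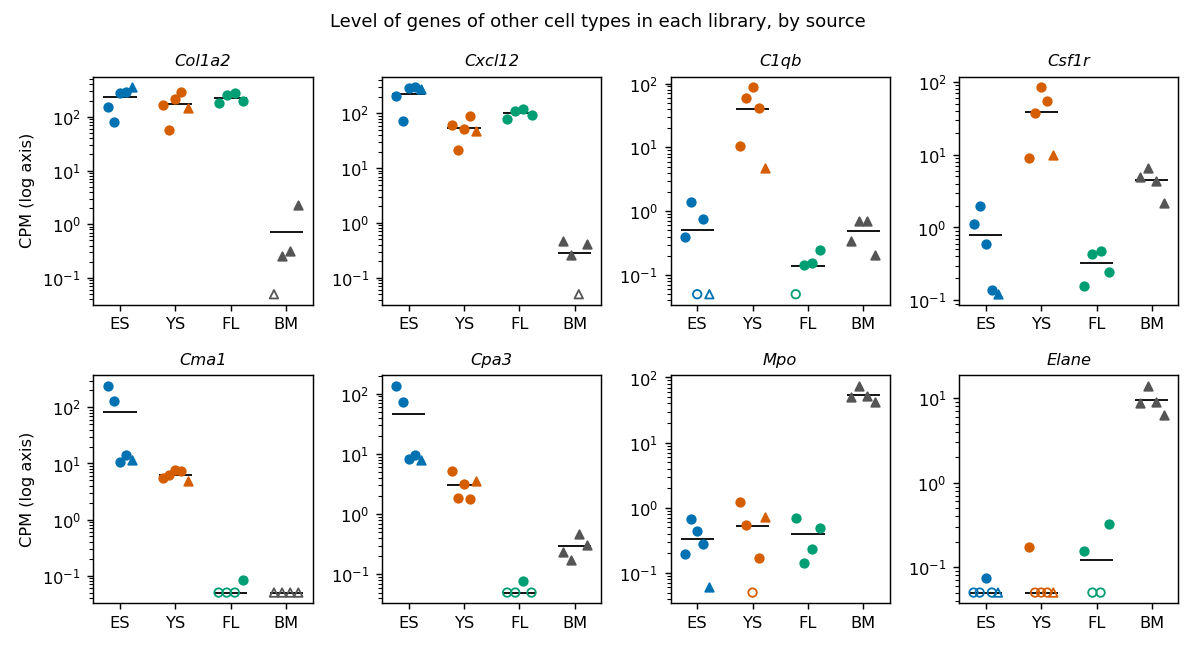
TMM-scaled CPM of 8 genes of other cell types in each library (log axis; open symbols mark 0 counts, drawn at 0.05 CPM), with a line at the mean of each source. The stromal genes Col1a2 and Cxcl12 are near 0 in bone marrow, the macrophage genes C1qb and Csf1r are highest in yolk sac, the mast cell genes Cma1 and Cpa3 are highest in ES a and ES b, and the granule genes Mpo and Elane are highest in bone marrow.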

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

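Tests of stroma genes across series, of their co-expression, and of the slopes and ratio of Lin28b, H19 and Igf2 were chosen after the results were seen. The splits and the counts within a series were chosen before. The prediction for the glycolysis slope was written before its result, but the stroma score it uses was added after seeing the data. The slope and the counts within a series both use genes called in these data. A group here is 1 of 130 genes, or 1 measure of a library such as total counts, in the 4 or 5 libraries of a source. In each of 467 groups, the highest or lowest library was compared with the rest by Dixon's ratio. A library far from the others was held by 48 groups. Chance would give about 1 in 20, or 23.4, only for independent groups and genes picked without regard to their values. Some genes were named after their values were seen, and genes of a library can vary together, so the excess is descriptive. Of the 48 groups, yolk sac b held 18, ES b 8, bone marrow 1 held 5 and yolk sac d held 3. Another 8 libraries held 1 or 2, and ES c, ES d, yolk sac a and bone marrow 2, 3 and 4 held none.

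Yolk sac b was high for Igf2bp3 (167 CPM), Polm (20.4), Bach2 (239.7), Ndn (3.51), Cd19 (1502), and H2-K1 (1333). It was also high for H2-T23 (276), Trim66 (21.2), H2-Q4 (556), Mzb1 (655), Hist1h1c (34656) and Kdr (10.5). It was low for Igf2 (6.65), Meis1 (1.66) and Mcm3 (385). It also had a high share of counts in its 10 largest genes (14.7%), few genes with counts (12229) and a high endothelial share (0.00465%). ES b was high for Lin28b (150.7), Igf2bp1 (150.7), Igf2bp3 (127), Socs2 (322), Bcl2 (32.5), Csf2rb (10.5) and Thy1 (8.26), and low for Xrcc4 (17.6). Bone marrow 1 was low for H2-Eb1 (80.4) and Aldoa (117) and high for Bhlhe41 (47.2), Grb10 (4.51) and Hist1h1c (5238). Yolk sac d was high for Aldoc (33.4), Csf2rb (71.8) and Trpc4 (3.93). Yolk sac c was low for Ms4a1 (51.1) and Zmat3 (2.10). ES a was high for Polm (13.3) and low for Nov (73.1). Fetal liver c was high for Arid3a (187) and H2-Q4 (77.2). Fetal liver b was high for Pbx1 (3.83) and the myeloid share (0.0112%), fetal liver d for Trpc4 (16.3), and fetal liver a low for the stroma share (0.114%). ES 5 was high for Aldoc (4.62) and Myh6 (6.62), and yolk sac 5 for Myh6 (13.8) and total counts (14323000).

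Other splits of the same libraries were fitted alike. Splits that mix sources add source differences to the spread within groups, so they tend to call few genes whatever set the libraries apart. A real count that few splits reach thus shows only that the libraries separate by these labels, not why. Even for that, chance can be excluded only if libraries are independent. No label states that, and close libraries, such as fetal liver a with c and b with d, would leave fewer independent splits. For the prenatal sources against bone marrow, 1 of 100 splits called as many genes (6877, highest other 2060). ES-derived against yolk sac cells gave 1 of 100 (3660, highest other 2549) and ES-derived against fetal liver cells 1 of 100 (4854, highest other 3966). Against bone marrow, ES-derived cells gave 1 of 100 (7502, highest other 4533), yolk sac cells 1 of 100 (6541, highest other 2700) and fetal liver cells 1 of 35 (5606, highest other 0). For yolk sac against fetal liver cells, 2 of 100 splits called as many (1993, highest other 3095). The higher split put yolk sac b with the fetal liver libraries against the other 4 yolk sac libraries, which points to a structure of the samples around yolk sac b.

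Stromal genes were almost absent from bone marrow libraries, although the labels state growth on OP9 for all cells. The time of bone marrow cells on OP9 is not given. Little or no culture of these cells can therefore not be told apart from their source in any comparison with bone marrow. Library series is excluded as the whole cause, since the lower share of ES 5 and yolk sac 5 was 19.3 times the highest bone marrow share. A candidate explanation is RNA of OP9 cells in the prenatal libraries, although the gate on CD19+B220+ cells would remove them: within sources the 23 stroma genes rose and fell together, with a median correlation of 0.828 against at most 0.227 in 1000 random lists. Col1a2 reached 350 CPM and Cxcl12 stood at 228 ± 94.3 CPM in ES-derived cells, and 0 of the list's genes are in another list. A difference between the progenitors of the sources in these genes stays open, untested.

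Fetal program genes were higher in the prenatal sources, and all 7 called genes kept direction and an adjusted p under 0.05 within the second series, which argues against library series. RNA of OP9 cells is argued against for Lin28b, Igf2bp1, Igf2bp3, Mycn and Plag1, whose median slope on the stroma level within sources was -0.159, where stroma genes had 0.449 to 1.25. The slope of Igf2bp1 had an SE of 0.434. ES b and yolk sac b had the lowest stroma scores (-1.28 and -1.21) and were flagged above as high for some of these genes. The argument thus rests in part on these libraries, and no slope without them was fitted. For H19, stroma and progenitors cannot be told apart, since the tables go both ways. Its counts per stroma count differed by a factor of 58.0 between sources (ES-derived 0.0295, yolk sac 1.71, fetal liver 0.746), but its slope within sources was 1.39 (SE 0.34), above the stroma genes. The same holds for Igf2, with a slope of 0.438 (SE 0.29) near the edge of the stroma range. Developmental age may explain the other genes, as a hypothesis from the same data, and days in culture were not tested.

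Glycolysis and hypoxia genes were higher in the prenatal sources, and all 20 called genes kept direction and an adjusted p under 0.05 within the second series, which argues against library series. Stromal RNA and the progenitors themselves cannot be told apart for this list: the median slope on the stroma level was 0.358 (median SE 0.202), within its error of the lowest stroma slope of 0.449. Density and oxygen in culture, and the source itself, stay open and were not tested.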

How the results depend on the processing

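The alternatives that leave out both ES b and yolk sac b, or the genes that track stroma, were chosen after seeing the data. Against 6877 genes for the prenatal sources and bone marrow, the alternatives with a new fit gave 6866 (RLE scaling) to 8691 (no series term), and 4897 to 7531 when leaving out 1 library. Dropping the 276 called genes that track stroma left 6601 without a new fit. That count does not test the part of stromal RNA in the remaining calls. ES-derived against fetal liver cells stayed within 1.5 times its count of 4854, with 4110 with the letters as a replicate block, and 3878 to 5864 when leaving out 1 library. ES-derived against yolk sac cells gave 2390 genes with only the compared libraries, against 3660, while the same alternative gave 5679 for ES-derived against fetal liver cells. Against 1993 genes for yolk sac and fetal liver cells, the 12 lettered libraries gave 1128 with the letters as a replicate block and 1250 unblocked. The count was 665 with only the compared libraries and 4081 without both ES b and yolk sac b. Leaving out 1 library gave 989 (without fetal liver d) to 3712 (without yolk sac b). Deviations from the source means had a median correlation of 0.0709 between same-letter libraries of different sources and -0.0161 between the other pairs. Whether letters pair the libraries was not tested. Yolk sac against bone marrow cells ran from 4040 (without yolk sac 5) to 7467 (without yolk sac b) when leaving out 1 library, and gave 7613 without both ES b and yolk sac b and 7997 with no series term. Without both ES b and yolk sac b, yolk sac against fetal liver cells passed ES-derived against yolk sac cells (3968). The cause was not tested. With an estimated correlation 4 of 11 lists stayed called for prenatal sources against bone marrow, 5 of 13 for ES-derived against yolk sac, 4 of 9 for ES-derived against fetal liver and 0 of 8 for yolk sac against fetal liver cells; fry called 19 lists in the first.

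No called named gene reversed. Against bone marrow 82 of 103 called named genes were never lost, and between yolk sac and fetal liver cells 44 of 75. Values that reversed were not called: Arid3a against bone marrow ran from -0.12 (without ES 5) to 0.23 (without yolk sac 5), and Cd19 from -0.14 (without ES 5) to 0.38 (without yolk sac 5), with -0.052 within a series. Cd19 between ES-derived and yolk sac cells was 0.0096 without both ES b and yolk sac b. Ptprc between yolk sac and fetal liver cells was -0.013 without the series term, -0.030 with upper quartile scaling, and -0.050 (without yolk sac c) to 0.066 (without ES b). The stroma share between ES-derived and fetal liver cells ran from -0.0312 (without fetal liver a) to 0.00698 (without ES b). The cause was not tested. The low-count filter removed no gene, so it tests nothing, and the share of heavy chain V genes with its alternatives was not run, since none are listed. In simulated counts, 2-fold changes were recovered for 48 of 100 genes for the prenatal sources against bone marrow. The comparisons among prenatal sources recovered 71 or 72 of 100.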

Other observations

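The values of this part were chosen after they were seen and were not tested. Mast cell genes differed among the ES-derived libraries, with Cma1 at 242 and 131 CPM in ES a and b and at 10.7, 13.9 and 11.7 CPM in ES c, d and 5. Macrophage genes differed among yolk sac libraries, with C1qb at 10.7, 58.3, 86.7, 41.1 and 4.76 CPM in a, b, c, d and 5. The granule gene Mpo stood at 49.8, 74.5, 51.3 and 42.3 CPM in the 4 bone marrow libraries. Adipoq, an adipocyte hormone, stood at 15.6, 14.2 and 16.9 CPM in ES c, d and 5, and at 3.93 and 1.34 CPM in ES a and b.

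Hist1h1c, a linker histone gene, stood at 34656 CPM in yolk sac b and at 1136 to 5238 CPM elsewhere. The 59 listed histone genes took 8.94% of counts there and 2.18 to 5.80% in the other libraries. Fzd6, Cacna1h, Trim12a and Trim30d were under 0.1 CPM in ES-derived cells and over 5 CPM in each other source, and 9 genes, with Rprl3 and St6galnac2 among them, were over 5 CPM in ES-derived cells alone and under 0.5 CPM elsewhere. The same limits gave 24 and 19 genes for bone marrow, 0 and 7 for yolk sac, and 0 and 0 for fetal liver.

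The Y-linked gene Eif2s3y stood at 1.02 CPM in yolk sac b, against 27.6 to 65.8 CPM in the other yolk sac libraries. Yolk sac b may thus differ from them in sex, which was not tested. ES b, from VE-cadherin+ cells, had 150.7 CPM of Igf2bp1 against 54.2 to 65.4 in the Flk1+ libraries, and 9.60 CPM of H19 against 25.5 to 65.1. ES b also spent 16 days on OP9, against 13 or 14 in the Flk1+ libraries, and had the lowest stroma score of the ES-derived libraries (-1.28). Plated cell, days on OP9 and stroma level cannot be told apart here.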
